A study of Escherichia coli with 15 samples.

How the data were processed

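RNA from 5 groups of Escherichia coli MG1655 was measured on Affymetrix E. coli Antisense Genome Arrays, with 3 arrays labelled per group. The deposited values are probe set intensity values on a linear scale, made with MAS5 per the submitters' processing notes, and the MAS5 version and scaling target are not given in the sources used here. The 2% trimmed means of the 15 columns lay within a ratio of 1.05, under the limit of 5% set in the plan, so the deposited scale was kept. The array carries 7312 probe sets, of which 4345 measure genes, 2886 intergenic sequence, 59 foreign sequence and 22 are array controls. Gene names came from the platform annotation for 4192 gene probe sets with 1 K-12 gene and from the locus tag for 40, while 72 without a match kept the name in the file and 41 match several genes. The names of 126 gene probe sets mark them as shared between sequences.

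The plan counted 15 arrays, and this was changed once the values were seen. In the fliA deletion the third column was a weighted sum of columns 1 and 2. Among 6295 probe sets where those differ by more than 100, 99.9% had one of 8 weights, such as 0.65 in 2019, 0.55 in 1361 and 0.5 in 969. In the flhDC deletion a weight of 0.524 held in 1050 of 1898 such probe sets, and the third column was identical to wild-type column 1 in 2422 probe sets and to wild-type column 2 in 1424. The third pre-induction column had a weight of 1.31 in 253 of 2927 probe sets and 1.241 in 224, with 23.8% in the 8 commonest weights. Pre-induction column 1 lay between columns 2 and 3 in 99.8% of 3772 probe sets. That share alone does not settle which of columns 1 and 3 was made from the others. The 2% trimmed mean of column 1 was 1000.43, within the 1000.13 to 1000.78 of the 11 arrays kept. That of column 3 was 1004.98, outside this range. Column 3 of the fliA deletion, flhDC deletion and induced groups also lay outside it, at 1017.73, 978.574 and 1025.71. These values argue against column 1 having been made from the others. The third induced column had a weight of 0.498 in 236 of 3793 and 0.497 in 174, with 17.0% in the 8 commonest weights, and was identical to the third pre-induction column in 1010, of which 516 had values of 100 or more. Any other pair of columns shared at most 8 values of 100 or more, outside the pairs named here. In the pre-induction and induced groups most values of the third column were thus not accounted for by these weights, which set only a lower bound on the share. In wild type the 8 commonest weights held 1.53%. How these columns arose is not given in the sources used here. They were left out of the main fit, leaving 11 arrays taken as independent, 3 of wild type and 2 of each other group, and fits with all 15 columns and with pre-induction column 3 in place of column 1 were added as alternatives.

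Signals were transformed as log2 of the value plus an offset of 70, the median over the independent arrays of the 10th percentile of genes. Genes were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, an intensity trend in eBayes and 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 4345 gene probe sets of each comparison, and adjusted p under 0.05 counted as changed. SE is the limma standard error of a log2 fold change, and SD is that of deposited signals. Intergenic probe sets were fitted apart from the genes. Within groups the correlation of log2 values was 0.958 to 0.976 in wild type, 0.919 in the fliA deletion, 0.987 in the flhDC deletion, 0.974 in the pre-induction control and 0.922 in the induced group. The median signal of foreign sequence lay between 36.9 and 141 on the independent arrays. The level of background was set per array as the 95th percentile of 58 foreign probe sets, and where every array of a group lay at or below it a fold change is given as at least the ratio to that level. Where both groups did, no fold change is given.

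Genes were grouped into 22 lists written before the data were examined, covering the flagellar regulon, neighbours of the deleted genes, curli, type 1 fimbriae, carbon uptake, anaerobic respiration, ribosomal proteins, stress responses, iron, amino acids, nitrogen, phosphate, sugar genes, strain variants and prophages. The members fliB, ecnB, micF, ymgF and tfaR had no probe set. List shifts were tested with camera at a preset correlation of 0.01, adjusted over 88 list tests in the first 4 comparisons and separately in the fifth, and repeated with an estimated correlation and with fry. Counts adjusted over the list alone used the genes of that list only. The rule for naming genes took flhD, flhC and fliA, the 10 largest increases and decreases among changed genes whose groups did not overlap, up to 4 members with the smallest adjusted p of each list with a change or shift, and up to 4 members of each flagellar list that did not pass. Overlaps were compared with independent lists, and the overlap, correlation and covariance of the deletions with 100 simulations of unchanged groups and, as an added alternative, with the wild-type arrays split between the comparisons.

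The scripts were tested on simulated data with known fold changes in the 4345 genes. The noise was independent and normal, with the same SD of a gene in all groups, in 1 run per comparison. Within-group correlations in the data ranged from 0.919 in the fliA deletion to 0.987 in the flhDC deletion. The shares below therefore hold for the simulated setting only. In the fliA deletion comparison 25.4% of 2-fold, 88.1% of 4-fold and 98.5% of 8-fold changes were recovered, with 4 false calls. In the flhDC deletion comparison the shares were 41.8%, 89.6% and 100%, with 8 false calls, and in the induction comparison 41.8%, 91.0% and 95.5%, with 7. Between the deletions they were 41.8%, 82.1% and 100%, with 12, and for the pre-induction control against wild type 46.3%, 83.6% and 98.5%, with 9. Alternatives were quantile normalization, median centring, no offset, an offset of 280, leaving out the lowest 25% or 50% of probe sets, only the 2 groups in the fit, no intensity trend, robust eBayes, array weights, a block for the replicate number, gene and intergenic probe sets together, a threshold of 0.01, an added 2-fold threshold and each array left out in turn. No comparison had 3 independent arrays in both groups, so no counts from other splits of the samples are given. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.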

Results

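RNA of Escherichia coli MG1655 was hybridised to 15 Affymetrix E. coli Antisense Genome Arrays, labelled as 5 groups of 3. The groups were a wild type, a strain without fliA, which encodes the flagellar sigma factor sigmaF, a strain without flhDC, which encodes the master regulator of flagellar genes, and a strain with a plasmid-borne fliA gene sampled at 0 and at 5 min of induction with anhydrotetracycline. All cultures were sampled at an optical density of 0.2, and the labels state that the series asks which genes FlhDC and sigmaF control. The array held 7312 probe sets, of which 4345 measured genes and 2886 measured intergenic sequence. The deposited values were already on one scale, with 2% trimmed means between 979 and 1026, and the small number of arrays limits the precision of every value below. In each of the 4 groups other than wild type, at least part of the values of the third column followed from other columns of the table. The share traced to the commonest weights was nearly all in the fliA deletion and a minority in the pre-induction and induced groups. It is only a lower bound. In 99.8% of 3772 probe sets where pre-induction columns 2 and 3 differed by over 100, column 1 lay between them. The same share in wild type was 33.1% to 60.3%. The third columns of these 4 groups were left out, so that each had 2 arrays and wild type had 3. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between arrays, which may be technical.

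The manipulated genes had lower signals than wild type in the strains labelled as lacking them, and fliA its highest after induction. The fliA signal was 11228 ± 2453 (SD, n = 3) in wild type, 273 ± 21.0 (n = 2) in the fliA deletion and 196 ± 70.6 (n = 2) in the flhDC deletion. It was 9799 ± 961 (n = 2) in the pre-induction control and 92635 ± 43590 (n = 2) after induction. The flhD signal was 5203 ± 394 in wild type and 1091 ± 47.4 in the flhDC deletion, and that of flhC was 2114 ± 112 and 281 ± 12.2. The flhD signal of the flhDC deletion thus stayed above the foreign-sequence levels of 466 and 374 on its 2 arrays, and whether the probes lie within the deleted part is not given in the sources used here. In the fliA deletion the signals of flhD and flhC were 3932 ± 1888 and 1593 ± 285, and neither differed from wild type at the threshold (adjusted p = 0.27 and 0.25). Without fliA deletion array 1 the flhD log2 fold change was 0.02 in place of -0.48.

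**Figure D1:**
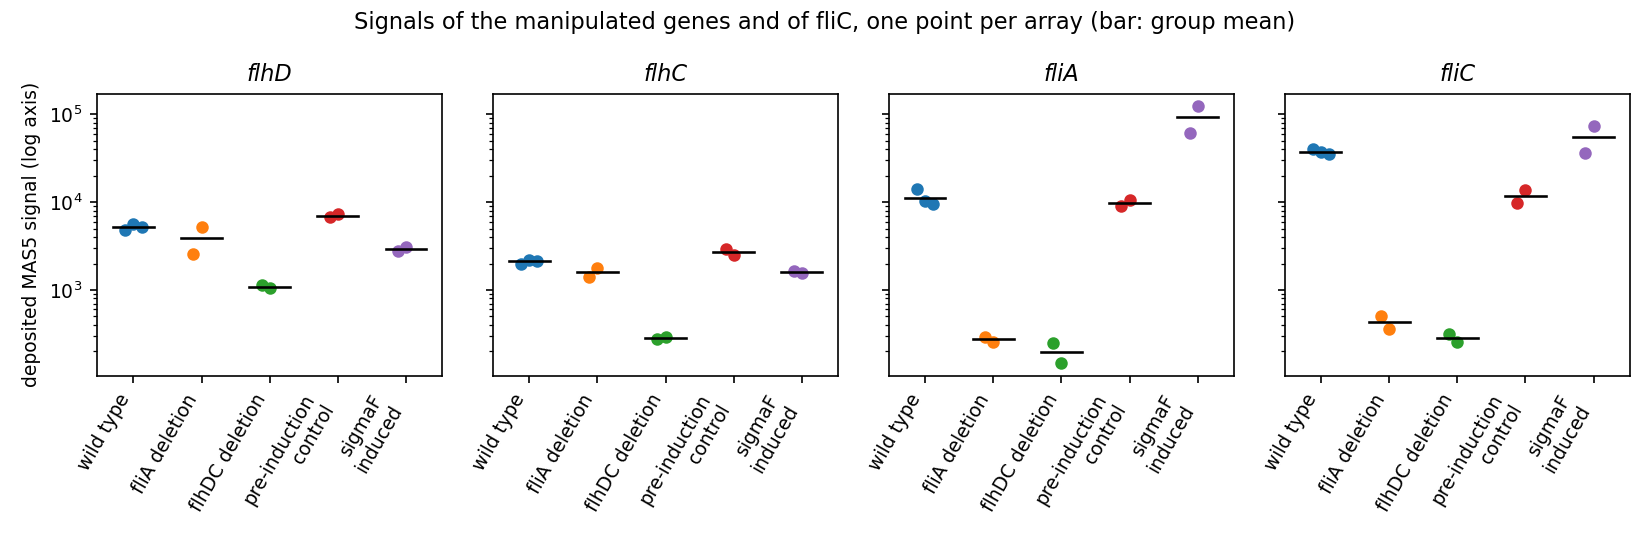
Deposited MAS5 signal on a log axis of flhD, flhC, fliA and fliC in the 5 groups, with one point per independent array and a bar at the group mean. The fliA signal lies between 146 and 288 on the 4 deletion arrays, between 9120 and 14018 on the wild-type and pre-induction arrays, and at 61812 and 123458 after induction.

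Loss of sigmaF lowered all 8 genes of the filament, junction and chaperone list and all 13 of the motor and chemotaxis list, while 25 of 29 hook, basal body and export genes did not pass the threshold. The shifts of the first 2 lists had adjusted p = 0.083 and adjusted p = 0.065 with an estimated correlation. Flagellin (fliC) had a signal of 431 ± 102 (n = 2) in the fliA deletion against 37749 ± 2682 (n = 3) in wild type, at least 78.3-fold lower (adjusted p = 1.3e-08). The stator gene motB was at least 8.27-fold lower, with 107 ± 72.7 against 3995 ± 436 (adjusted p = 4.9e-07), and the chemotaxis adaptor gene cheW at least 21.0-fold lower, with 397 ± 173 against 10192 ± 1579 (adjusted p = 6.6e-05). The aspartate receptor gene tar fell by 3.56 on the log2 scale, from 10831 ± 751 to 876 ± 306 (adjusted p = 2.2e-06). Over all genes, 129 of 4345 changed, of which 29 were higher and 100 lower.

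All 8 genes of the filament, junction and chaperone list fell in the fliA deletion, among them the cap gene fliD, the hook-filament junction gene flgK and the anti-sigma factor gene flgM, with log2 fold changes of -2.99 ± 0.32 (SE), -2.40 ± 0.33 and -2.77 ± 0.36. All 13 genes of the motor and chemotaxis list fell too, with cheZ at least 7.11-fold and motA at least 7.14-fold lower and cheY at -3.31 ± 0.29. The counts adjusted over the list alone were also 8 and 13. Both lists shifted down in camera (adjusted p = 2.0e-19 and 3.1e-34), with adjusted p = 0.083 and adjusted p = 0.065 with an estimated correlation. Of 29 hook, basal body and export genes 4 fell, or 8 adjusted over the list alone. These were fliA itself, the hook genes flgD (-0.76 ± 0.18) and flgE (-1.05 ± 0.22) and the switch gene fliM (-1.04 ± 0.24), while flgA (-0.66 ± 0.18, adjusted p = 0.065) and fliN (-0.78 ± 0.24, adjusted p = 0.10) did not pass. That list shifted down in camera (adjusted p = 1.3e-09), with adjusted p = 0.13 with an estimated correlation. Of 8 other flagellar-linked genes 6 fell, or 8 adjusted over the list alone, including flxA, ycgR (the brake protein that binds cyclic di-GMP), pdeH (a cyclic di-GMP phosphodiesterase, yhjH in the fixed list) and rdcA (yjdA in the fixed list). The first 3 had log2 fold changes of -4.24 ± 0.55, -3.88 ± 0.43 and -3.08 ± 0.31, rdcA was at least 15.9-fold lower, and the list shifted down in camera (adjusted p = 2.7e-16; adjusted p = 0.070 with an estimated correlation).

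Outside the flagellar lists, 7 of 75 amino acid biosynthesis genes fell in the fliA deletion, with thrA at -1.55 ± 0.17, thrB at -1.15 ± 0.18 and leuB at -1.42 ± 0.21. Adjusted over the list alone, 8 were lower and 1 higher. The 7 lay among the 38 members lower after sigmaF induction, of which 3 passed as lower in the fliA deletion after quantile normalization. Of 19 heat shock genes 4 fell (7 adjusted over the list alone), namely the chaperone genes dnaK (-1.55 ± 0.29), dnaJ (-1.43 ± 0.31) and groS (-1.23 ± 0.22) and the protease gene lon (-1.17 ± 0.17). Of 55 ribosomal protein genes 2 fell, rpsE (-1.45 ± 0.26) and rplR (-1.41 ± 0.30), the same count as adjusted over the list alone. The amino acid list lost its shift after quantile normalization (adjusted p = 0.71), where its median was 0.03 in place of -0.12. These 3 lists shifted down in camera (adjusted p = 9.3e-05, 8.2e-08 and 3.2e-12), with adjusted p = 0.71, adjusted p = 0.22 and adjusted p = 0.50 with an estimated correlation. In the list of mar and sox genes, acrA (-1.11 ± 0.24) and tolC (-1.36 ± 0.25), which encode parts of a multidrug efflux pump, fell out of 17 members. Adjusted over the list alone 2 were lower and 2 higher. In the anaerobic respiration list the formate channel gene focA (-0.78 ± 0.19) was the 1 of 38 genes past the threshold, also adjusted over the list alone. In the iron uptake list 1 of 37 genes passed as higher, fepG, whose signals lay at or below the foreign-sequence level in both strains, or 4 adjusted over the list alone (camera adjusted p = 0.0086; adjusted p = 0.83 with an estimated correlation). Among the largest increases were the tRNA gene proM (2.80 ± 0.70, adjusted p = 0.047), the formate dehydrogenase gene fdoG (at least 3.04-fold), the tryptophanase leader gene tnaC (at least 1.79-fold) and the nickel transporter gene nikB (at least 2.70-fold). None of the 31 general stress genes, 42 carbon uptake genes or 9 type 1 fimbriae genes passed in limma, with 5, 4 and 0 of them at an unadjusted p under 0.05. The dim signals of fliA deletion array 1 were raised, with a 10th percentile of 344 over genes against 44.0 to 104 on the other 10 independent arrays. The median log2 fold change of all genes was 0.26, against -0.02 without fliA deletion array 1 and 0.54 without fliA deletion array 2.

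The count of 129 genes was 51 (4 higher) without wild-type array 2, 26 with array weights and 45 without an intensity trend. It was 1213 (843 higher) with all 15 columns as separate arrays and 1338 (1077 higher) without fliA deletion array 2. After quantile normalization, where the median log2 fold change of all genes was 0.02, 85 genes were higher and 121 lower, so that 41.3% were higher in place of 22.5%. Of the 35 genes named for this comparison that passed 17 kept their call in every fit.

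**Figure D2:**
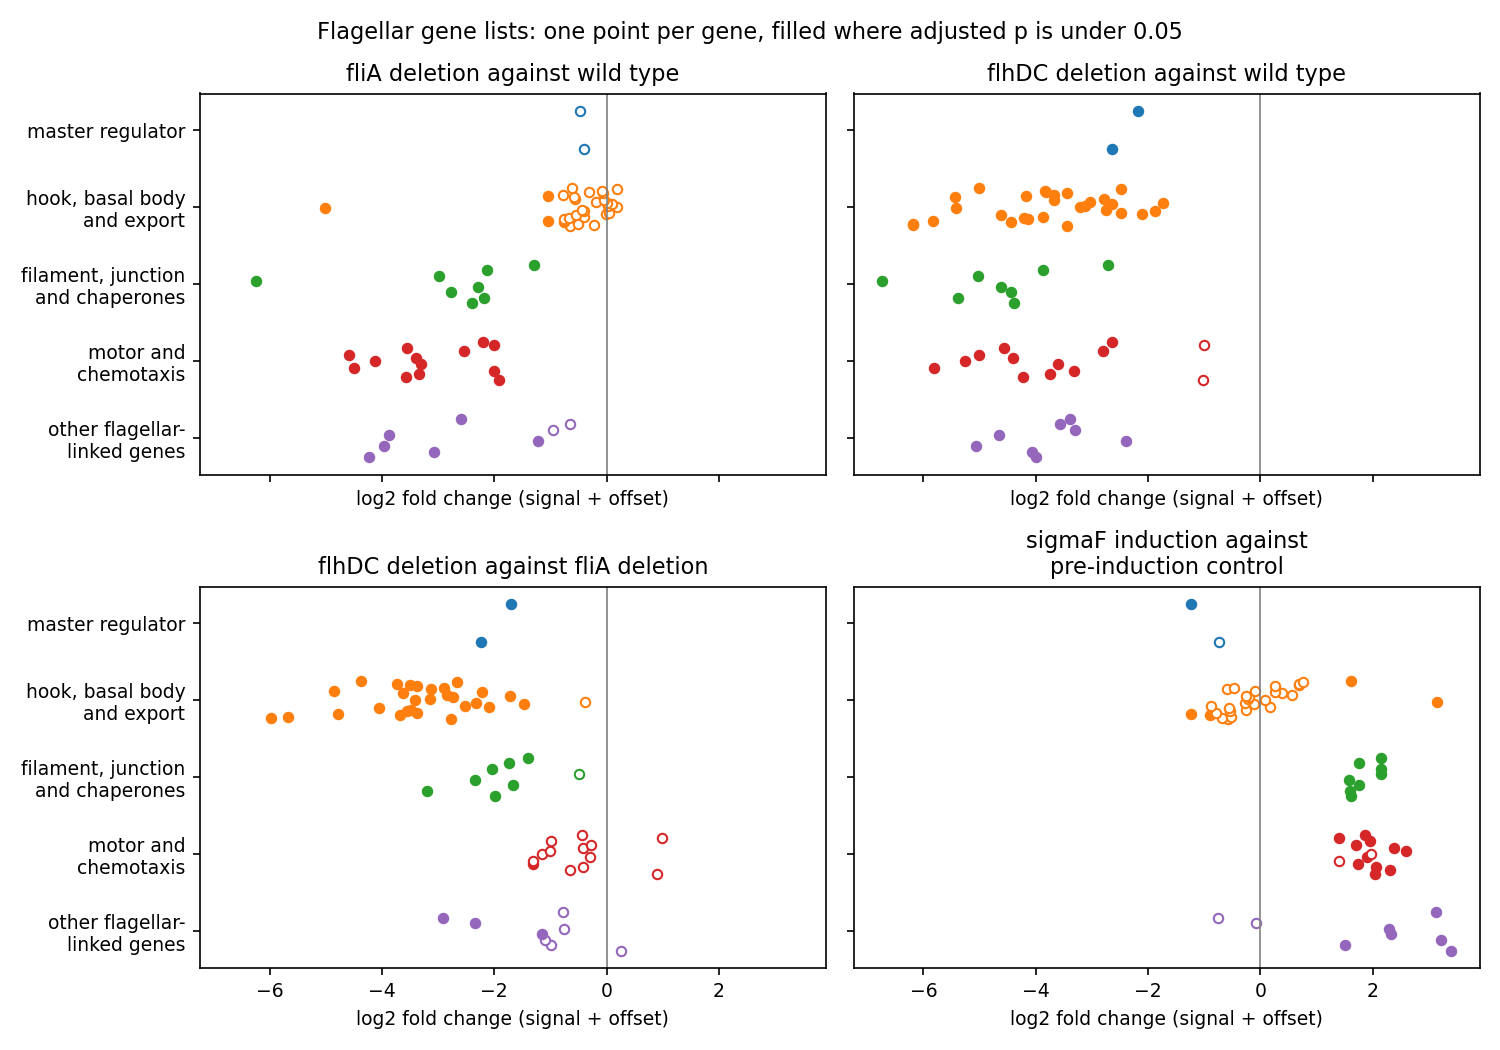
Log2 fold change of each gene in the 5 flagellar lists in 4 comparisons, with one point per gene, filled where the adjusted p is under 0.05. In the fliA deletion 4 of 29 hook, basal body and export genes are filled, against 29 of 29 in the flhDC deletion, while all 8 filament, junction and chaperone genes are filled in both.

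In the flhDC deletion nearly the whole flagellar regulon was lower than in wild type, and genes of the general stress list were higher. The cause of that rise was not settled. Of the 52 flagellar and chemotaxis genes, 50 fell, or 52 adjusted over the list alone. The rod genes flgB and flgC had signals of 63.0 ± 28.8 and 105 ± 13.6 (n = 2) in the flhDC deletion against 9538 ± 871 and 12818 ± 2410 (n = 3) in wild type, at least 22.8-fold and 30.4-fold lower (adjusted p = 2.2e-10 for both). The periplasmic acid chaperone genes hdeA and hdeB rose from 1232 ± 248 to 17175 ± 789 and from 497 ± 169 to 6924 ± 341 (adjusted p = 2.6e-08 and 1.2e-06). Over all genes 147 changed, of which 63 were higher and 84 lower.

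All 29 hook, basal body and export genes fell in the flhDC deletion, including the hook gene flgE (at least 18.1-fold lower) and fliL (at least 9.37-fold lower). This shift held in camera with a preset correlation (adjusted p = 8.0e-91) and with an estimated one (adjusted p = 0.0038). All 8 filament, junction and chaperone genes fell, with fliC at least 90.3-fold, fliD at least 16.3-fold and flgL at least 11.6-fold lower. Of 13 motor and chemotaxis genes 11 fell, or 13 adjusted over the list alone, with motB at least 9.54-fold and cheW at least 24.2-fold lower. The receptor genes aer (-1.01 ± 0.38, adjusted p = 0.22) and trg (-1.01 ± 0.30, adjusted p = 0.099) did not pass. All 8 other flagellar-linked genes fell, with ymdA at least 9.24-fold, ycgR at least 14.6-fold and rdcA at least 18.3-fold lower. Counts adjusted over the list alone were 29, 8 and 8 for the lists that fell throughout, and both flhD and flhC fell with either adjustment. Camera gave adjusted p = 1.1e-26, 4.7e-31, 1.7e-22 and 9.2e-07 for the filament, motor, other flagellar-linked and master regulator lists, and adjusted p = 0.065, adjusted p = 0.068, adjusted p = 0.065 and adjusted p = 0.068 with an estimated correlation.

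Of 31 general stress (RpoS) genes 13 rose in the flhDC deletion, or 20 adjusted over the list alone, and none fell. Besides hdeA and hdeB these included the acid resistance regulator gene gadE, from 16.9 ± 6.26 to 477 ± 0.495 (at least 1.21-fold higher, adjusted p = 0.0054), the glutamate decarboxylase gene gadB (at least 2.79-fold higher, adjusted p = 0.017), psiF (1.66 ± 0.26) and the cyclopropane fatty acid synthase gene cfa (1.17 ± 0.21). The list shifted up in camera (adjusted p = 2.2e-22), also with an estimated correlation (adjusted p = 0.043). Outside the list the acid regulator genes gadX (at least 6.15-fold) and evgA (at least 4.37-fold), the glycogen gene glgS (2.18 ± 0.36) and the osmoprotectant transporter gene proW (at least 1.51-fold) were among the largest increases. So was sra, which encodes a stationary-phase ribosome-associated protein (1.99 ± 0.40). In the iron uptake list cirA (0.87 ± 0.22), fhuF (1.12 ± 0.25) and bfd (1.16 ± 0.22) rose out of 37, also adjusted over the list alone (camera adjusted p = 0.0096; adjusted p = 0.83 with an estimated correlation). In the curli list csgF (1.51 ± 0.37) rose out of 7, and adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.028; adjusted p = 0.71 with an estimated correlation). Single genes fell in the envelope stress list (surA, -1.22 ± 0.25, 1 of 17), the heat shock list (dnaJ, -1.28 ± 0.31, 1 of 19) and the ribosomal protein list (rpsO, -0.80 ± 0.20, 1 of 55, where sra, counted in that list by its older symbol, rose). The ribosomal list had a median of 0.00 (camera adjusted p = 0.74), and after quantile normalization one of -0.15 with a shift down (adjusted p = 0.0073). None of the 38 anaerobic respiration genes passed in limma, with 3 at an unadjusted p under 0.05, though that list shifted down in camera (adjusted p = 0.030; adjusted p = 0.91 with an estimated correlation).

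The count of 147 genes (63 higher) was 71 (8 higher) and 82 (11 higher) without flhDC deletion array 1 and 2, 338 with only the 2 groups in the fit, 1272 with array weights and 467 with all 15 columns as separate arrays. Of the 34 genes named for this comparison that passed, 20 kept their call in every fit.

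A direct comparison of the deletions asked which genes depend on FlhDC beyond the presence of sigmaF. Of 29 hook, basal body and export genes 28 were lower in the flhDC deletion (adjusted p = 0.0095 for the list with an estimated correlation), with flgB at 63.0 ± 28.8 (n = 2) in the flhDC deletion and 8157 ± 155 (n = 2) in the fliA deletion, at least 19.6-fold lower (adjusted p = 1.6e-09). The gene fliZ, which lies beside fliA and encodes a regulator of RpoS-dependent genes, was at 150 ± 24.2 against 4695 ± 1906, at least 10.8-fold lower (adjusted p = 1.3e-06). The acid resistance gene hdeA was higher, at 17175 ± 789 against 1316 ± 175 (adjusted p = 1.8e-07). Over all genes 201 differed, 92 higher and 109 lower in the flhDC deletion.

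Of the 52 flagellar and chemotaxis genes 38 were lower in the flhDC deletion than in the fliA deletion (42 adjusted over the list alone, of which 1 was higher). They included 28 of 29 hook, basal body and export genes, with flgC at least 21.3-fold, flgE at least 8.65-fold and fliL at least 6.20-fold lower, and the shift held in camera (adjusted p = 1.1e-52; adjusted p = 0.0095 with an estimated correlation). The exception was fliA, whose signals lay at or below the foreign-sequence level in both strains, so that no difference could be measured. Of the 8 filament, junction and chaperone genes 7 were lower, with flgL at least 2.42-fold and flgN at -2.34 ± 0.41, while fliC lay at or below the foreign-sequence level in both strains, so that no difference could be measured. Of 13 motor and chemotaxis genes 1 was lower, the methyltransferase gene cheR (at least 1.45-fold), and adjusted over the list alone 4 were lower and 1 higher. The genes motB and cheW lay at or below the foreign-sequence level in both strains, and motA and cheZ did in the fliA deletion. A further fall could not be measured for them. Of 8 other flagellar-linked genes 3 were lower (4 adjusted over the list alone), namely ymdA (at least 5.83-fold), yecR (at least 1.29-fold) and rdcB (yjcZ in the fixed list, at least 2.21-fold). The same limit held for rdcA, at or below that level in both strains. For the filament and other flagellar-linked lists camera gave adjusted p = 1.3e-06 and adjusted p = 0.0013, with adjusted p = 0.37 and adjusted p = 0.50 with an estimated correlation. Both flhD (-1.70 ± 0.27) and flhC (at least 3.79-fold) were lower, with camera adjusted p = 4.4e-04 for that list and adjusted p = 0.15 with an estimated correlation.

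Of 31 general stress genes 10 were higher in the flhDC deletion than in the fliA deletion, and adjusted over the list alone 13 were higher and 1 lower. They included hdeB (3.65 ± 0.33), the DNA protection gene dps (1.78 ± 0.27), hdeD (at least 2.43-fold) and cfa (1.32 ± 0.23). Camera gave adjusted p = 8.8e-14, and adjusted p = 0.065 with an estimated correlation. Of 19 heat shock genes 4 were higher (5 adjusted over the list alone), groS (1.68 ± 0.24), groL (0.83 ± 0.21), lon (0.79 ± 0.19) and hslV (0.81 ± 0.21), with camera adjusted p = 1.4e-04 and adjusted p = 0.44 with an estimated correlation. In the ribosomal protein list rpsE (1.36 ± 0.29) was the 1 of 55 genes past the threshold, also adjusted over the list alone (camera adjusted p = 1.8e-11; adjusted p = 0.52 with an estimated correlation and 0.70 after quantile normalization). In the anaerobic respiration list focA (1.09 ± 0.21) was higher and glpA (at least 2.14-fold) and dmsB, whose signals lay at or below the foreign-sequence level in both strains, lower out of 38 (camera adjusted p = 0.012; adjusted p = 0.91 with an estimated correlation). In the curli list csgF was higher (at least 1.84-fold) and csgC lower (at least 1.52-fold) out of 7, or 3 higher and 1 lower adjusted over the list alone. Of 37 iron uptake genes 5 were lower, among them fepA (-1.33 ± 0.32) and fecC (at least 1.72-fold), and adjusted over the list alone 5 were lower and 1 higher. The dim signals of fliA deletion array 1 were raised. This can make dim genes such as glpA, dmsB, csgC and fecC appear lower in the flhDC deletion. The amino acid list had 2 of 75 genes higher and 1 lower, with a median of -0.01 and a camera shift up (adjusted p = 0.023; adjusted p = 0.91 with an estimated correlation) that was down and lost after quantile normalization (adjusted p = 0.70).

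The count of 201 genes was 45 (10 higher) without flhDC deletion array 1, the same without array 2, 46 with array weights, and 96 without an intensity trend. It was 1603 (1341 lower) without fliA deletion array 2 and 1830 (1391 lower) with all 15 columns as separate arrays. The median log2 fold change of all genes was -0.37 (0.00 after quantile normalization). It was -0.04 without fliA deletion array 1 and -0.66 without fliA deletion array 2. Of the 30 genes named for this comparison that passed 12 kept their call in every fit.

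Together, 36 genes were lower in both deletions, of which 23 belonged to the flagellar and chemotaxis lists. Lists drawn independently would share 1.93, which leaves out the shared wild-type arrays, and unchanged groups that share these arrays had 0 in 100 simulations, which leaves out the effects. Outside these lists the shared genes included flxA, ynjH, ycgR, pdeH, rdcA and rdcB, all from the list of other flagellar-linked genes, and dnaJ. The 4 genes higher in both deletions were hflC, hisL, tnaC and tyrT, named after their values were seen (0.420 expected for independent lists). Across all 4345 genes, which are not independent replicates, the fold changes of the deletions correlated at r = 0.41, against 0.40 for unchanged groups that share wild-type arrays, while their covariance was 0.184 against 0.0640. Without the flagellar and chemotaxis lists the r was 0.29, so part of the r came from those genes. That value lay below the 0.40 of unchanged groups, which was simulated over all genes. No covariance without these lists was computed. Part of the overlap may come from the shared wild-type arrays. With these split so that the comparisons shared none, 1 array for one deletion and the other 2 for the other in each of the 6 ways, 17 to 29 genes were lower in both deletions (0.491 to 1.252 for independent lists), from fewer arrays in each comparison. The r was then 0.19 to 0.35 and the covariance 0.103 to 0.166. With shared arrays the r was 0.26 without fliA deletion array 2, and the overlap was 106 with all 15 columns as separate arrays.

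At 5 min of sigmaF induction all 8 filament, junction and chaperone genes and 11 of 13 motor and chemotaxis genes were higher than in the pre-induction control, and 25 of 29 hook, basal body and export genes did not pass the threshold. The shifts of the first 2 lists had adjusted p = 0.19 and adjusted p = 0.15 with an estimated correlation. The fliA signal itself rose from 9799 ± 961 to 92635 ± 43590 (n = 2 each, adjusted p = 1.2e-04). Flagellin (fliC) rose from 11741 ± 2918 to 55035 ± 26428 (adjusted p = 0.0010), motA from 1639 ± 423 to 10150 ± 788 (adjusted p = 6.0e-04) and tar from 5002 ± 181 to 20473 ± 8876 (adjusted p = 0.0012). Of 75 amino acid biosynthesis genes 38 fell, with leuB going from 10422 ± 852 to 1799 ± 195 (adjusted p = 8.2e-05), and the list shift had adjusted p = 0.12 with an estimated correlation. Over all genes 277 changed, of which 90 were higher and 187 lower.

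Of the 52 flagellar and chemotaxis genes 21 rose and 3 fell after induction, or 25 and 7 adjusted over the list alone. All 8 filament, junction and chaperone genes rose with either adjustment, with fliD at 2.16 ± 0.35, the chaperone gene fliT at 2.14 ± 0.32 and flgK at 1.62 ± 0.36. Of 13 motor and chemotaxis genes 11 rose (13 adjusted over the list alone), with motB at 2.39 ± 0.32 and the serine receptor gene tsr at 1.86 ± 0.28. The genes cheW (1.40 ± 0.49, adjusted p = 0.12) and cheZ (1.97 ± 0.59, adjusted p = 0.066) did not pass. Of 8 other flagellar-linked genes 6 rose, also adjusted over the list alone, where 1 was lower, with flxA at 3.40 ± 0.61, rdcA at 3.23 ± 0.48 and ynjH at 3.13 ± 0.46. These 3 lists shifted up in camera (adjusted p = 1.0e-10, 9.2e-17 and 2.5e-06), with adjusted p = 0.19, adjusted p = 0.15 and adjusted p = 0.28 with an estimated correlation. Of 29 hook, basal body and export genes, fliA and fliZ (1.62 ± 0.34) rose and flgD (-0.90 ± 0.20) and flgE (-1.24 ± 0.24) fell, the same counts as adjusted over the list alone. The master regulator gene flhD fell (-1.23 ± 0.27, adjusted p = 0.014), and flhC (-0.74 ± 0.21, adjusted p = 0.055) passed only when adjusted over the list alone (camera adjusted p = 0.012 for the list; adjusted p = 0.30 with an estimated correlation and 0.068 after median centring). Increases outside the flagellar lists included amyA (2.69 ± 0.32), the neighbour of the fliDST operon that encodes a cytoplasmic amylase, ves (2.43 ± 0.38) and cvrA (2.42 ± 0.40).

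Of 75 amino acid biosynthesis genes 38 fell after induction (48 adjusted over the list alone) and none rose, with leuA at -2.54 ± 0.26, metB at -2.14 ± 0.23, thrC at -1.65 ± 0.19 and hisD at -2.89 ± 0.60. The list median was -0.96 and camera gave adjusted p = 4.8e-28, with adjusted p = 0.12 with an estimated correlation. Of 42 genes of CRP-dependent carbon uptake 8 fell (13 adjusted over the list alone), among them the galactitol gene gatY (-1.57 ± 0.29) and the ribose genes rbsD (-1.89 ± 0.26) and rbsK (-1.46 ± 0.34). The list had camera adjusted p = 1.4e-04 and adjusted p = 0.17 with an estimated correlation. Of 9 type 1 fimbriae genes 3 rose with either adjustment, the main subunit gene fimA (2.30 ± 0.45) and fimC and fimI (at least 1.46-fold and 1.80-fold higher), with camera adjusted p = 7.5e-05 and adjusted p = 0.37 with an estimated correlation. Other large decreases were the thiamine synthesis gene thiC (at least 4.30-fold), the porin gene nmpC (-2.53 ± 0.22) and the lipid A modification genes arnB (-2.77 ± 0.71) and arnC (at least 3.70-fold). The heat shock genes grpE (1.01 ± 0.21) and ibpB (1.52 ± 0.42) rose out of 19, or 4 higher and 3 lower adjusted over the list alone. In the general stress list cfa (0.96 ± 0.23) rose out of 31, also adjusted over the list alone (camera adjusted p = 0.035; adjusted p = 0.68 with an estimated correlation, 0.15 after quantile normalization and 0.082 after median centring). In the iron uptake list exbD (-1.51 ± 0.22) and sufD (at least 1.20-fold) fell out of 37. In the envelope stress list fkpA (-1.32 ± 0.22) fell out of 17, where 6 were higher and 2 lower adjusted over the list alone. In the mar and sox list acrA (-1.26 ± 0.27) and nfo (-1.39 ± 0.33) fell out of 17, where 2 were higher and 5 lower. Of 27 nitrogen limitation genes glnK (-1.21 ± 0.33) passed over all genes and none adjusted over the list alone. In the ribosomal protein list rpmF (1.36 ± 0.29) rose out of 55, also adjusted over the list alone, and the list median of 0.34 (camera adjusted p = 0.0012; adjusted p = 0.91 with an estimated correlation) was -0.25 with a shift down after quantile normalization (adjusted p = 0.015).

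The count of 277 genes was 97 and 65 without pre-induction array 1 and 2, 464 without induced array 1, 172 after median centring, and 103 without an intensity trend. It was 1126 with all 15 columns as separate arrays and 6 with only the 2 groups in the fit, which left 2 residual degrees of freedom. The 24 flagellar and chemotaxis genes were 11, 8, 28, 14, 10, 34 and 1 in those fits. Of the 44 genes named for this comparison that passed, 4 kept their call in every fit.

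**Figure D3:**
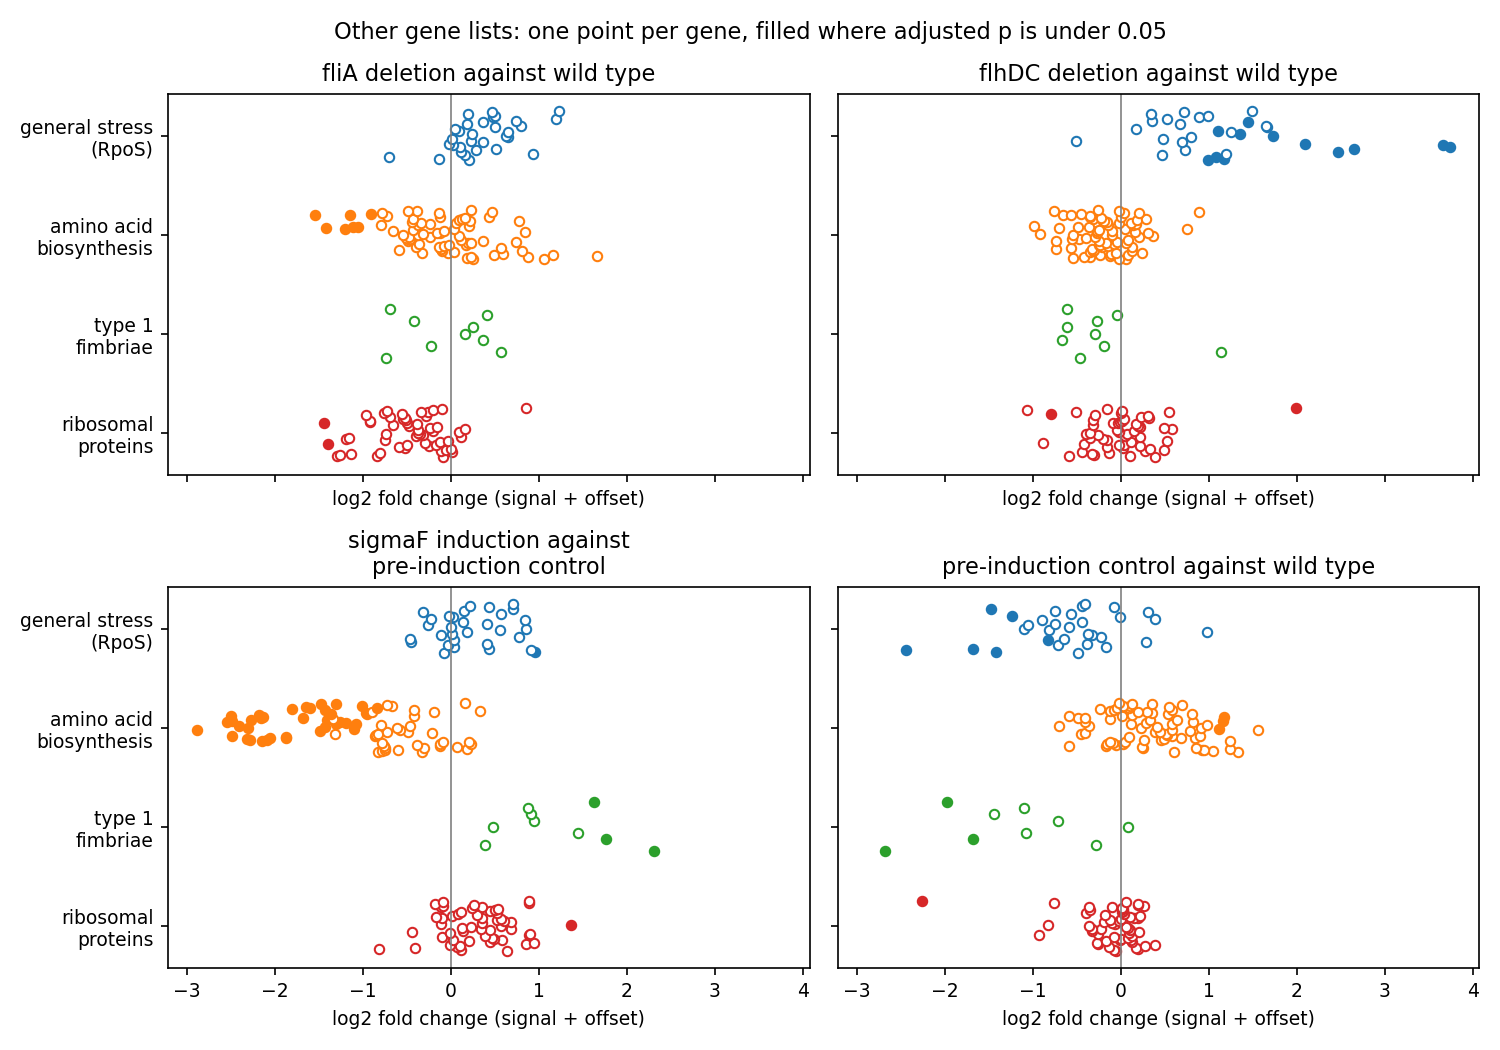
Log2 fold change of each gene in 4 lists outside the flagellar regulon in 4 comparisons, with one point per gene, filled where the adjusted p is under 0.05. The 13 filled general stress genes of the flhDC deletion lie above 0 and the 38 filled amino acid genes after induction lie below it, while the ribosomal list after induction turned from a median of 0.34 to -0.25 with quantile normalization.

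Genes lower without sigmaF and higher after its induction included filament, motor and chemotaxis genes and genes outside the flagellar lists. These 2 comparisons shared no arrays, and 32 genes met both conditions against 2.07 for independent lists (two-sided Fisher's exact test across genes, p = 1.6e-31, as a description). Of these, 20 belonged to the flagellar and chemotaxis lists, including fliA itself, fliC, fliD, flgK, motA, motB, tar and tsr. The 12 outside them included ynjH, flxA, ycgR, pdeH, rdcA and rdcB, all members of the fixed list of other flagellar-linked genes. The rest were ves, galK, modA, modB, mutY and ykfB. Some of the 12 were named after their values were seen. Of all 32, 28 were lower in the flhDC deletion as well. Over the 52 flagellar and chemotaxis genes, which are not independent replicates, the fold changes correlated at r = -0.79 (Spearman rho = -0.68), and over all genes at r = 0.15. The 52 include fliA, whose direction in both comparisons was set by the design, and no r without it was computed. In addition 25 genes were lower in both the fliA deletion and the induced arrays (4.30 for independent lists), leuB and thrC among them. The 32 genes were 16 and 13 without pre-induction array 1 and 2, 20 without induced array 2, 13 without an intensity trend and 1 with only the 2 groups in each fit.

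**Figure D4:**
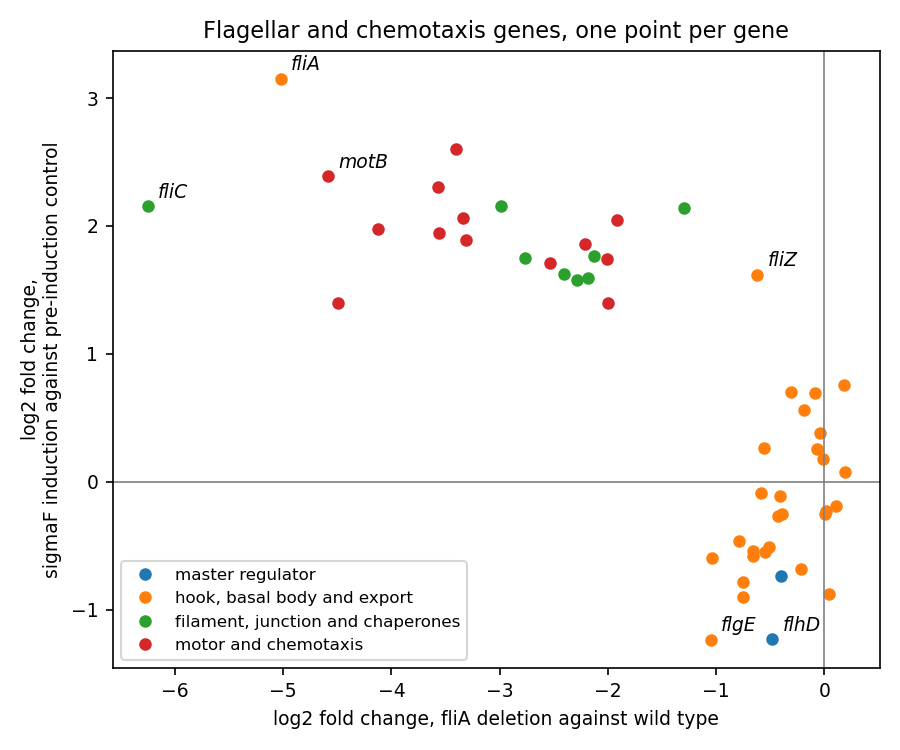
Log2 fold change in the fliA deletion against wild type (x axis) and after sigmaF induction against the pre-induction control (y axis) for the 52 flagellar and chemotaxis genes, one point per gene. Filament, motor and chemotaxis genes lie at the upper left and most hook, basal body and export genes near the centre (r = -0.79).

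The pre-induction control, which carries the plasmid, was compared with wild type as a secondary comparison of the reference groups. The fliC signal was 11741 ± 2918 (n = 2) against 37749 ± 2682 (n = 3) in wild type (adjusted p = 0.0051), fimA was 1907 ± 225 against 12745 ± 2265 (adjusted p = 0.0041) and dps was 465 ± 36.6 against 2903 ± 701 (adjusted p = 1.1e-04). The log2 fold change of fliA was -0.18 ± 0.28 (adjusted p = 0.92), and 0.04 after quantile normalization. Over all genes 127 changed, 75 higher and 52 lower.

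Of the 52 flagellar and chemotaxis genes 3 fell, fliC, cheY (-1.26 ± 0.29) and tar (-1.10 ± 0.26), or 7 adjusted over the list alone. Within their lists, adjusted over the list alone, 6 of 8 filament, 5 of 13 motor and chemotaxis and 1 of 29 hook, basal body and export genes fell. Of 8 other flagellar-linked genes rdcA (-1.90 ± 0.44) and ynjH (-1.76 ± 0.42) fell, or 5 adjusted over the list alone. For the filament, motor and other flagellar-linked lists camera gave adjusted p = 4.0e-07, adjusted p = 1.6e-08 and adjusted p = 2.4e-06, each with adjusted p = 0.36 with an estimated correlation. Of 31 general stress genes 6 fell (9 adjusted over the list alone), including cfa (-1.42 ± 0.21) and elaB (at least 3.41-fold), with camera adjusted p = 6.2e-11 and adjusted p = 0.18 with an estimated correlation. Of 9 type 1 fimbriae genes 3 fell (5 adjusted over the list alone), with fimI at least 2.38-fold and fimC at least 1.41-fold lower beside fimA, with camera adjusted p = 4.0e-07 and adjusted p = 0.36 with an estimated correlation. Of 42 carbon uptake genes the galactitol genes gatA (-1.33 ± 0.33), gatB (-1.12 ± 0.28) and gatC (-1.25 ± 0.23) and the maltose gene malK (at least 1.11-fold) fell, and adjusted over the list alone 5 were lower and 1 higher (camera adjusted p = 0.025; adjusted p = 0.46 with an estimated correlation). In the ribosomal protein list sra (-2.26 ± 0.40) fell out of 55, also adjusted over the list alone, and the list shifted up after quantile normalization (adjusted p = 0.016; 0.080 and down without it). The largest increases included speB (2.58 ± 0.21), truB (2.38 ± 0.22), the housekeeping sigma factor gene rpoD (2.00 ± 0.24) and the insertion sequence gene insA1 (2.69 ± 0.40, a probe set marked as shared between sequences). Of 75 amino acid genes hisG (1.12 ± 0.23), leuB (1.16 ± 0.21) and metB (1.17 ± 0.21) rose, or 6 adjusted over the list alone, and of 37 iron uptake genes exbD (0.82 ± 0.20), or 2. Camera gave adjusted p = 2.7e-04 for both lists, with adjusted p = 0.71 and adjusted p = 0.69 with an estimated correlation. The heat shock genes clpP (1.04 ± 0.26) and clpX (1.10 ± 0.23) rose out of 19 with either adjustment.

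The count of 127 genes was 23 and 16 without pre-induction array 1 and 2, 75, 46 and 68 without wild-type array 1, 2 and 3, 192 without fliA deletion array 1, 62 after median centring, and 48 without an intensity trend. It was 65 with the replicate block, 294 with only the 2 groups in the fit, 747 with array weights and 530 with all 15 columns as separate arrays. The 3 flagellar genes were 0 without pre-induction array 1, 1 without array 2, 1 without each wild-type array in turn and 6 without fliA deletion array 1. Of the 27 genes named for this comparison that passed 5 kept their call in every fit.

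Of the 12 measured neighbours of the deleted genes, 1 rose in the flhDC deletion (otsB, 1.11 ± 0.27), 1 after induction (amyA) and 1 in the pre-induction control against wild type (yedD, 0.80 ± 0.18). Over the 5 comparisons no member of the phosphate starvation list (17 genes), the list of lactose, arabinose and rhamnose genes (13) or the list of loci that vary between MG1655 stocks (10) passed in limma, with 14, 13 and 5 results at an unadjusted p under 0.05. The e14 and Rac prophage list (16 genes) had 2 results past the threshold in all comparisons, and the nitrogen limitation list 3.

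Of the intergenic probe sets, fitted apart from the genes, 17 of 2886 passed in the fliA deletion, 8 higher and 9 lower. The counts were 75 in the flhDC deletion, 124 after induction, 54 between the deletions and 68 in the pre-induction control against wild type. The reverse-strand probe set at 1975164 to 1975289, a position taken from its name with no genome build stated, had log2 fold changes of -4.74 ± 0.42 in the fliA deletion, -5.98 ± 0.42 in the flhDC deletion and 3.39 ± 0.46 after induction. The reverse-strand probe set at 3653935 to 3654037 was higher in the flhDC deletion (4.71 ± 0.25, adjusted p = 8.3e-09).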

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

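All tests of explanations in this part were chosen only after the results were seen. The list changes that they address are repeated from the results above. Those lists were written before the data were examined.

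The bla probe set, which measures a plasmid resistance gene and is not used in any comparison, had signals of 37685 ± 10810 (SD, n = 2) in the pre-induction control and 74466 ± 18157 (n = 2) after induction. It drew attention because the highest value on the 7 arrays of the other groups was 169.

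The dim signals of fliA deletion array 1 were raised. Its intergenic median was 2.63 times the highest of the other arrays, while its array-control median of 27.9 lay within their 13.9 to 64.5, which is consistent with material that hybridises along the chromosome, such as genomic DNA. Its foreign-sequence median of 66.8 lay within the others' range of 36.9 to 141, against optical background or scaling of the whole array. The other fliA deletion array had a 10th percentile of 51.4 over genes, within the 44.0 to 104 of the other groups, against loss of sigmaF as the cause.

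Of 75 amino acid biosynthesis genes 38 fell after sigmaF induction, with leuA, metB and hisD among them, and the list shift had adjusted p = 0.12 with an estimated correlation. The median of all genes moved by 0.0252 on the log2 scale and that of the list by -0.96, against array scaling with a few very bright genes. The list median of induced arrays against wild type was -0.77, with 30 of 75 genes lower, against a raised pre-induction control as the whole cause, although the control lay above wild type by 0.33. Repression that follows the sigmaF level stays open. Of the 38 genes that fell, 7 were also lower in the fliA deletion, or 3 after quantile normalization, and 0 higher in either fit. The median of the 38, at -0.37, lay within their SD of 0.50 and was -0.05 without fliA deletion array 1. Loss of sigmaF also does not test an excess of it. An effect of anhydrotetracycline or of the 5 min of sampling also stays open, since no array with inducer and without plasmid-borne fliA was analysed here.

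Of 31 general stress genes 13 rose in the flhDC deletion, with hdeA, hdeB and gadB among them (adjusted p = 0.043 for the list with an estimated correlation). The median of all genes moved by -0.0804 and that of the list by 1.08, against array scaling. Of the list, 10 genes were higher than in the fliA deletion, a list shift that did not pass with an estimated correlation. The fliZ signals were 6968 in wild type, 4695 in the fliA deletion and 150 in the flhDC deletion. These values go with loss of fliZ or of another gene that FlhDC still drives without sigmaF. Any such gene would give the same values, so fliZ itself was not singled out. In the pre-induction control fliZ was at 5365, and the list shifted down against wild type. After induction fliZ was at 18077, and the list shifted up against that control. Neither shift passed with an estimated correlation, but in those groups the list did not move opposite to fliZ. The comparisons of the flhDC deletion with wild type and with the fliA deletion use the same flhDC deletion arrays. Another difference confined to those arrays could therefore also raise the list in both. The ribosomal protein list had a median of 0.00401 with an SD of 0.448 and 1 of 55 genes lower, but shifted down after quantile normalization (median -0.15, adjusted p = 0.0073, against 0.74 without it and 0.83 with median centring), so a culture further along its growth curve cannot be told apart, as members went both ways.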

How the results depend on the processing

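The fit with all 15 columns, the fit with pre-induction column 3 in place of column 1, the split of the wild-type arrays, and leaving out fliA deletion array 1 in comparisons that do not use it, were chosen only after the results were seen. The flagellar and chemotaxis counts of the 3 comparisons that involve a deletion lay within 1.5 times the main count throughout, at 18 to 29, 49 to 50 and 30 to 43 with single arrays left out. All these genes were lower, except 2 of 44 that were higher between the deletions with 15 columns. With pre-induction column 3 in place of column 1, induction changed 252 genes, of which 24 were flagellar, and the control differed from wild type in 111, of which 3 were. Where an array was left out, a lone array was assumed to vary like the other groups. The labels do not say whether replicate numbers pair arrays. The differences of arrays 1 and 2 had correlations of -0.24 to 0.24 between groups, and 0.03 between the pre-induction and induced groups. With 1 difference per group this check cannot exclude pairing. A paired fit with the replicate number as a block gave 88, 110, 247, 160 and 65 genes in the order of the comparisons below and 23, 50, 24, 37 and 1 flagellar genes. Of the 43 list shifts in camera 3 held with an estimated correlation and 21 with fry. The median foreign-sequence signal of 36.9 to 141 limits what dim genes can show. The cause of the changes below was not tested, apart from fewer arrays or degrees of freedom and stricter thresholds.

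For the fliA deletion, 129 genes became 206 with quantile normalization, 45 without a trend, 26 with array weights, 1213 with 15 columns, 52 at a threshold of 0.01 and 51 to 1338 with single arrays left out. For the flhDC deletion, 147 became 338 with only the 2 groups, 1272 with weights, 467 with 15 columns, 97 at 0.01 and 71 to 219 with arrays left out. After induction, 277 became 172 with median centring, 6 with the 2 groups, 103 without a trend, 1126 with 15 columns, 100 at 0.01 and 65 to 464 with arrays left out. Between the deletions, 201 became 96 without a trend, 46 with weights, 1830 with 15 columns, 62 at 0.01 and 45 to 1603 with arrays left out. For the pre-induction control against wild type, 127 became 62 with median centring, 294 with the 2 groups, 48 without a trend, 747 with weights, 65 with the replicate block, 530 with 15 columns, 53 at 0.01 and 16 to 192 with arrays left out.

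The 24 flagellar and chemotaxis genes changed after induction became 14 with median centring, 1 with the 2 groups, 10 without a trend, 13 at 0.01 and 8 to 28 with arrays left out. The 3 of the pre-induction control became 1 with median centring, 5 with an offset of 280, 17 with the 2 groups, 1 without a trend, 20 with weights, 1 with the replicate block, 14 with 15 columns, 1 at 0.01 and 0 to 6 with arrays left out. The 36 genes lower in both deletions became 106 with 15 columns, 17, 23 and 21 with wild-type array 1, 2 or 3 alone for the fliA deletion and the other 2 for the flhDC deletion, and 27 to 52 with arrays left out, and the r of the deletions 0.52 with the lowest 50% left out, 0.21, 0.31 and 0.34 in those splits, 0.33 and 0.19 with array 1 or 3 alone for the flhDC deletion, and 0.26 to 0.46 with arrays left out. The 32 genes lower in the fliA deletion and higher after induction became 1 with the 2 groups, 13 without a trend, 14 at 0.01 and 13 to 35 with arrays left out, and the flagellar r -0.74 with quantile normalization and -0.80 to -0.74 with arrays left out.

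The intergenic counts follow. In the fliA deletion 17 became 9 with median centring, 46 and 65 without the lowest 25% and 50%, 65 with the 2 groups, 2 without a trend, 41 with robust eBayes, 2 with weights, 10 with the replicate block, 1271 with 15 columns, 26 with genes and intergenic probe sets together, 7 at 0.01 and 7 to 2021 with arrays left out. In the flhDC deletion 75 became 48 with median centring, 169 with the 2 groups, 29 without a trend, 479 with weights, 36 with the block, 0 in limma with 15 columns, 34 at 0.01 and 18 to 97 with arrays left out. After induction 124 became 60 with median centring, 43 with the 2 groups, 19 without a trend, 44 at 0.01 and 43 to 234 with arrays left out. Between the deletions 54 became 147 with the 2 groups, 18 without a trend, 4 with weights, 1300 with 15 columns, 21 at 0.01 and 13 to 1965 with arrays left out. For the pre-induction control 68 became 35 with median centring, 140 with the 2 groups, 45 without a trend, 205 with weights, 41 at 0.01 and 31 to 121 with arrays left out.

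Of the 43 list shifts, those of the amino acid list in the fliA deletion and between the deletions, the ribosomal list between the deletions and the general stress list after induction lost their call with quantile normalization, which gave 5 others, among them the ribosomal list in the flhDC deletion (down, adjusted p = 0.0073). With median centring 2 were lost and 2 gained. For the amino acid list in the fliA deletion, the median went from -0.12 to 0.03 (adjusted p = 0.71). Each named gene that reversed had not passed the threshold. With single arrays left out, flhD in the fliA deletion lay between -0.981 and 0.0199. Quantile normalization turned fliA (0.51) and fliC (0.22) between the deletions, where both lay at or below the foreign-sequence level in both strains and the sign means nothing, fliA in the pre-induction control (0.0369), the ribosomal list after induction (-0.25) and the amino acid list between the deletions (-0.0144, with camera up in the main fit), and median centring turned the same background difference of fliA (0.0375).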

Other observations

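The comparison of induced arrays with wild type and the division of the general stress list were chosen only after the results were seen.

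The genes below differed between the pre-induction control and wild type, and they were picked after their values were seen. The fimbrial subunit gene fimA had mean signals of 12745 in wild type, 1907 in the pre-induction control and 11936 after induction, and the induced arrays differed from wild type by -0.38 ± 0.41 (SE, adjusted p = 0.63). The insertion sequence gene insA1 had 985.5, 6714 and 1173, a difference of -0.01 ± 0.40 (adjusted p = 0.99). The genes leuB and metB were below wild type, at -1.33 ± 0.21 (adjusted p = 0.0016) and -0.97 ± 0.21 (adjusted p = 0.014). Of the genes that changed after induction, the induced level lay nearer to wild type than that of the control in 80 of 247 outside the flagellar lists and 10 of 30 within them. No share over all genes was computed. These genes were selected by a difference from the control, so spread of the control arrays alone can give such counts. Between the induced arrays and wild type 359 genes differed.

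Of the 8 acid resistance genes of the general stress list 5 rose in the flhDC deletion, with a median log2 fold change of 2.28, and of the other 23 genes 8 rose, with a median of 0.89, and neither part was tested as a set or against the other. Against the fliA deletion 5 genes of each part were higher, with medians of 2.14 and 0.47. In the fliA deletion against wild type 0 genes of either part passed in limma, with medians of 0.20 and 0.36.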
